A study of Homo sapiens with 4 samples.

How the data were processed

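RNA from 4 cultures of the melanoma line A2058 was labelled with biotin and read on Illumina bead arrays, per the labels' protocols. The 4 groups are parental and carmustine-selected stem-like cells, each in normoxia and in hypoxia, with 1 array per group. Groups were taken from the sample labels.

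The deposited non-normalized table gives for each probe a mean bead intensity on a linear scale, per the file headers, and judged from the values it was not background-subtracted. The same table gives a detection p-value per probe and array, per the file headers, in steps that correspond to 770 negative control beads. A further table deposited by the authors holds intensity values on a linear scale whose quantiles are the same on all 4 arrays, which is a property of the values and not stated in a header. The scanner software and its version, and the authors' normalization, are not given in the sources used here. Judged from its values, that further table was not background-subtracted either.

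The probe identifiers of the non-normalized table were out of step with its values. The table has 47323 lines of values and 47315 identifiers, and 98.0% of identifiers stand between 1 and 8 lines away from their values. By the printed identifiers, the signals of the first array had a Spearman rho of 0.015 with the further table, whose identifiers and values were in step. Each line of values was therefore given the probe whose values in the further table it matched along 1 ordered path, which brought that rho to 1.00. A check that does not use that table compared levels of 2 probes of the same gene over 6691 genes, with a Spearman rho of 0.018 by the printed identifiers and 0.456 after realignment. The 8 lines of values that matched no probe were not used here. The realignment was decided after the values were seen.

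Probes were named through the platform's annotation table, which can be old; 30112 probes had 1 gene symbol, 8 had several and 17195 had none, and only the first kind was used. They cover 20045 genes, and 19950 after Y-linked genes and XIST were left out. Of those probes, 30073 had a gene identifier in the RefSeq gene table of assembly GCF_000001405.40 (GRCh38.p14), and 0 probe symbols needed an update. Of the list names, 4 were matched under a newer symbol. Y-linked genes and XIST are not reported. No genome build is named for the array, so no coordinates are given.

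Signals were corrected for background and normalized with limma 3.58.1 in R 4.3.3, by its function for Illumina arrays, with negative control mean and SD inferred from the detection p-values. That step used normexp with an offset of 16, quantile normalization and log2. Of several probes of a gene, the one with the highest mean over the 4 arrays stands for it. Other detected probes are given where they differ, but not for the differences between hypoxia responses. A probe counts as detected at a detection p-value under 0.01. Folds were computed for genes detected on at least 1 array of a comparison. An undetected value was raised to the lowest normalized value among detected probes of that array, and such a fold is a bound, written as at least N-fold. Folds shrink toward 1 for dim genes because of the offset.

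With 1 array per group no test was made. A gene is called higher or lower at 2-fold, or a log2 fold of 1, which is a rule of size. The genes named were fixed by rule before the data were examined. They are, per comparison, the 8 highest and 8 lowest log2 folds among genes detected on both arrays, the 4 largest bounds in each direction, up to 4 members of each list with the largest log2 folds, and a panel of 23 genes of hypoxia, melanocytes, stem cells, alkylation repair and proliferation whatever their values, 1 of which had no probe used here. For the difference between hypoxia responses, the 8 largest in each direction among genes detected on all 4 arrays are named. The AKR1C, CT45A and GAGE families of near-identical copies are named as uncertain; probes of other named genes were not searched for near-identical copies.

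The 30 gene lists were written before the data were examined, with 637 entries, of which 588 had a probe used here. They cover hypoxia response, glycolysis, oxidative phosphorylation, melanocyte and pigment genes, dedifferentiated melanoma, stem cell associated genes, Notch, Hedgehog and Wnt signalling, epithelial-mesenchymal transition, matrix and collagen, DNA repair, glutathione and NRF2, drug transport, cell cycle, p53 targets, apoptosis, unfolded protein and integrated stress, heat shock, metallothioneins with the zinc exporter gene SLC30A1, interferon response, antigen presentation, inflammation, cholesterol and fatty acid synthesis, histones, cancer-testis genes, housekeeping genes, neural crest and neural genes, and markers of fibroblasts, keratinocytes, leukocytes and endothelial cells. For each list of at least 3 detected members, the median log2 fold was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. The melanocyte and pigment list also holds broadly expressed genes such as CDK2 and MYO5A. The percentile describes these arrays and is not a p-value.

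The steps were tested on simulated arrays. The realignment recovered the true line for 100% of 47315 simulated probes. For hypoxia in parental cells, simulated 3-fold changes were called in 98.5% of 67 genes and 4-fold changes in 100% of 66, and simulated 1.5-fold changes in 0% of 67. Among unchanged simulated genes, 5 of 10738 were called in that comparison and 6 of 10694 for hypoxia in stem-like cells. Of random unchanged lists, 3.5% lay outside the central 95% of matched lists. The changed genes were drawn only from brighter genes detected in normoxia in both cell states. Their recovery rates therefore say nothing about dim genes. The simulation covers array noise as assumed, not differences between cultures.

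Alternatives were no background correction, an offset of 50, median scaling in place of quantile normalization, a detection p-value under 0.05, genes detected on every array of a comparison, no detection filter, the mean of the detected probes of a gene, and the authors' further table. The authors' further table holds nearly the same values as the signals without background correction, at a median log2 distance of 0.005. These 2 alternatives therefore amount to 1 check. The number of arrays limits the precision of every value. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for folds, lists and plots.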

Results

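The series measured messenger RNA in A2058, an established human melanoma cell line, on 4 Illumina bead arrays. The labels cross 2 cell states with 2 oxygen conditions. Parental cells and a derivative called cancer stem-like cells were each grown in normoxia and in hypoxia. The derivative had been selected from the parental line with 100 uM carmustine, a chloroethylating drug that damages DNA by alkylation, over 6 months. Each of the 4 groups holds 1 array, so no difference here has a replicate check, none was tested, and every value describes these cultures only. The oxygen level and the length of the hypoxia exposure are not given in the sources used here.

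Between 16414 and 16927 of 47171 probes were detected on an array, which covered 10002 genes in parental normoxia, 10104 in parental hypoxia, 10034 in stem-like normoxia and 10288 in stem-like hypoxia. The median raw signal of detected probes was 295 and 301 in the parental cells and 259 and 267 in the stem-like cells. Normalized levels of the 8996 genes detected on all 4 arrays correlated across genes at r = 0.991 between the 2 parental arrays, 0.989 between the 2 stem-like arrays, 0.930 between the cell states in normoxia and 0.925 between them in hypoxia. Genes are not independent replicates, and these correlations describe the arrays.

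Technical error could be gauged only from genes with more than 1 detected probe. The SD between log2 folds of probes of 1 gene was 0.20 for hypoxia in parental cells, 0.22 for hypoxia in stem-like cells, 0.29 for the cell states in normoxia and 0.27 for the cell states in hypoxia. It leaves out the error between arrays and between cultures. The difference between the hypoxia folds of the 2 cell states had an SD of 0.31 over genes, which holds that error together with any true difference between the states. A gene counts as higher or lower below where its normalized signal differed by at least 2-fold.

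The first comparison asked which transcripts differed between hypoxia and normoxia in parental cells. Hypoxic parental cells carried more RNA of glycolytic enzymes and of known targets of the hypoxia-inducible factors, and few genes were lower. ENO2, the neuronal form of the glycolytic enzyme enolase, was 9.17-fold higher. NDRG1, a stress-responsive gene of the hypoxia response, was 5.17-fold higher, the membrane protein gene TMEM45A 4.67-fold and the mitophagy receptor gene BNIP3 4.65-fold. In all, 40 genes were higher and 8 lower among 10425 genes detected on either array.

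The other genes with the highest folds in parental hypoxia were TF, which encodes the iron carrier transferrin, at 3.97-fold, IGFBP3, which encodes a binding protein of insulin-like growth factors, at 3.94-fold, the mitochondrial adenylate kinase gene AK4 at 3.93-fold, and ANKRD37, a hypoxia-inducible factor target, at 3.48-fold. Of the hypoxia response list, 13 of 27 detected members were higher and 0 lower, and the list's median log2 fold of 0.87 exceeded those of all matched random lists (percentile 100). Of the glycolysis list, 6 of 21 were higher and 0 lower, with a median of 0.75 (percentile 100). They included SLC2A1, which encodes the glucose transporter GLUT1, at 3.04-fold, the aldolase gene ALDOC at 3.33-fold and PFKFB4, a regulator of glycolytic flux, at 2.63-fold. VEGFA, the angiogenic growth factor, was 2.20-fold higher by its brighter probe, while its other detected probe gave a log2 fold of -0.00. ADM, which encodes the vasodilator peptide adrenomedullin, stood at 1.32-fold.

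The matrix and collagen list had a median of 0.20 (percentile 100.0) with no member past 2-fold, led by the collagen-modifying enzyme gene PLOD1 at 1.71-fold. Its direction depends on the detection filter, since its median was 0.06 (percentile 91.9) with a detection p-value under 0.05 and -0.0041 (percentile 47.9) with no filter. The unfolded protein and integrated stress list had a median of 0.12 (percentile 99.3), the heat shock list -0.14 (percentile 0.48) and the inflammatory list -0.23 (percentile 0.42), which lay inside the range of random lists with a detection p-value under 0.05, at -0.09 (percentile 9.58). PROM1, which encodes the stem cell surface marker CD133, was 2.19-fold higher in hypoxia. The melanocyte genes PMEL, TYR and MLANA had log2 folds of 0.17, 0.05 and -0.05. Among genes that were lower, PLIN5, which encodes a lipid droplet protein, was 2.89-fold lower, the anion exchanger gene SLC26A4 2.28-fold, the replication factor gene GINS4 2.19-fold, and NMNAT1, ATF5, GPKOW, SLC30A1 and KAZN between 2.02-fold and 2.04-fold. SLC30A1 encodes a zinc exporter, and its second probe gave a log2 fold of -0.50. Second and further probes of KAZN gave -0.14 and -0.11.

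Genes detected on only 1 of the 2 parental arrays have a bound. SLAMF9 was at least 2.61-fold higher in hypoxia, PYGO2 at least 2.27-fold, BEND5 at least 2.16-fold and SERPINA5 at least 2.13-fold. IL12A was at least 1.87-fold lower, RSPO2 at least 1.71-fold, ARHGAP31 at least 1.68-fold and FAM222A at least 1.67-fold. Without background correction, 19 genes were higher and 1 lower, so the number of genes past 2-fold rests on that step.

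The same question was asked of the stem-like cells, where hypoxia again went with more RNA of hypoxia response and glycolysis genes. STC2, which encodes the secreted glycoprotein stanniocalcin-2, was 3.67-fold higher, TMEM45A 3.64-fold, IGFBP3 3.54-fold and ENO2 3.05-fold. COXFA4L2, a mitochondrial gene of the hypoxia response also known as NDUFA4L2, was at least 5.13-fold higher. AKR1C2, a steroid-metabolizing aldo-keto reductase, was 4.04-fold lower, and FABP7, a fatty acid binding protein of neural crest and glial cells, 2.98-fold lower. In all, 52 genes were higher and 19 lower among 10579.

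Of the hypoxia response list, 8 of 29 detected members were higher and 0 lower in stem-like cells, with a median log2 fold of 0.78 (percentile 100). Of the glycolysis list, 3 of 23 were higher and 0 lower, with a median of 0.48 (percentile 100), led by ENO2, the glycogen branching enzyme gene GBE1 at 2.13-fold and ALDOC at 2.07-fold. P4HA2, which encodes a collagen prolyl hydroxylase, was 2.24-fold higher, BNIP3 2.24-fold and ADM 2.16-fold, and VEGFA, NDRG1 and SLC2A1 stood at 1.74-fold, 1.72-fold and 1.61-fold. Other genes with high folds were ESPN, which encodes an actin-bundling protein, at 3.33-fold, the lipoprotein receptor gene VLDLR at 3.18-fold, DENND2A at 2.85-fold and the glutamate transporter gene SLC1A1 at 2.58-fold. By bounds, KISS1R was at least 3.82-fold higher, FGF11 at least 3.22-fold and BEND5 at least 2.69-fold.

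Genes of glutathione metabolism and the NRF2 response, which handle oxidants and electrophiles, lay below 0 in stem-like hypoxia. Of 21 detected members, 20 had a log2 fold below 0, none past 2-fold, and the median was -0.28 (percentile 0). The heme oxygenase gene HMOX1 was 1.80-fold lower and the glutathione transferase gene GSTM1 1.58-fold lower. Melanocyte genes had a median of -0.17 (percentile 0.71), with 1 of 14 past 2-fold, CAPN3 at 2.09-fold lower; with no detection filter the median was -0.03, inside the range of random lists. The inflammatory list had a median of 0.24 (percentile 99.6) with no member past 2-fold, led by IL11 at 1.93-fold and CCL20 at 1.79-fold. Matrix and collagen genes had a median of 0.17 (percentile 99.6), interferon response genes -0.15 (percentile 0.99) and oxidative phosphorylation genes -0.10 (percentile 2.25). The inflammatory median lay inside the range of random lists with no detection filter, at 0.145. The interferon median did so without background correction, with the authors' table and with no detection filter, at -0.07, -0.06 and -0.07.

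The remaining genes with the lowest folds in stem-like hypoxia were FCMR at 2.94-fold, ASPHD1 at 2.72-fold, SCARA5 at 2.54-fold, AKR1C4 at 2.35-fold, PHACTR1 at 2.19-fold and the matrix Gla protein gene MGP at 2.14-fold lower. AKR1C2 and AKR1C4 belong to a family of near-identical copies, so which member these probes measured is uncertain. By bounds, PLXND1 was at least 2.06-fold lower, MIR1282 at least 1.96-fold, DLX5 at least 1.93-fold and IDUA at least 1.79-fold. Without background correction, 12 genes were higher and 2 lower, and with median scaling in place of quantile normalization 34 were higher.

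The design also asks whether hypoxia folds differed between the cell states. Of the 26 members of the hypoxia response list detected on all 4 arrays, 23 had lower log2 folds in stem-like cells, with a median difference of log2 folds of -0.31 (stem-like minus parental, percentile 0 among matched random lists). This leaves out STC2 and COXFA4L2, with log2 folds of 1.88 and at least 2.36 in stem-like cells, which were not detected on either parental array. The 23 are counted by sign alone. They hold DDIT4, at 0.87 in both cell states, and MXI1 and JMJD6, which lay below 0 in both. A difference of at least 1 was reached downward by 4 members and upward by 1. Of the glycolysis list, 16 of 21 had a lower log2 fold, with a median difference of -0.19 (percentile 0.050). Other lists had larger downward differences than glycolysis. Melanocyte and pigment genes had a median difference of -0.30 (percentile 0.010; 11 of 13 below 0), interferon response genes -0.25 (percentile 0.100), glutathione and NRF2 genes -0.25 (percentile 0.010), and cholesterol and fatty acid synthesis genes -0.23 (percentile 0.150). Upward, the inflammatory list stood at 0.32 (percentile 99.7), the epithelial-mesenchymal transition list at 0.20 (percentile 98.7), the heat shock list at 0.14 (percentile 98.9) and the metallothionein list, by MT1X, MT2A and the zinc exporter gene SLC30A1, at 0.41 (percentile 99.6). Several of these differences lay inside the range of random lists under other settings. They are melanocyte and pigment genes with no detection filter at -0.11, and cholesterol and fatty acid synthesis genes with the mean of the detected probes at -0.09, without background correction at -0.10 and with the authors' table at -0.10. The inflammatory list did so with a detection p-value under 0.05 at 0.19, the heat shock list with median scaling at 0.04, and the epithelial-mesenchymal transition list without background correction at 0.12, with no detection filter at 0.10 and with the authors' table at 0.13. NDRG1 had log2 folds of 2.37 in parental and 0.78 in stem-like cells, and ENO2 of 3.20 and 1.61. Both genes were already brighter in stem-like normoxia than in parental normoxia, NDRG1 at a normalized log2 level of 10.80 against 6.62 and ENO2 at 7.72 against 6.05.

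The difference reached 1 on the log2 scale upward for 29 genes and downward for 31 of the 8996 genes detected on all 4 arrays. An SD of 0.30 for this difference was combined from the between-probe SDs of the 2 hypoxia folds, taken as independent. It was not measured on the differences themselves. The genes with the largest upward differences were PLIN5 at 1.73, UNC45A at 1.43, MAST3 at 1.40, NAV2 at 1.37, HINT3 at 1.36, SLC1A1 at 1.33, STIM1 at 1.26 and MRTFB at 1.25. Downward, GDF15, a stress-induced cytokine, stood at -1.76, BEST1 at -1.71, PLCXD1 at -1.70, NDRG1 at -1.59, ENO2 at -1.59, MIR3142HG at -1.51, PRKD2 at -1.39 and the acute-phase gene SERPINA3 at -1.33. Each of these differences rests on 1 probe per gene, and some rest on a value near the detection floor of 5.22 to 5.29. MAST3 stood at a normalized log2 level of 5.33 and SLC1A1 at 5.66 in stem-like normoxia. STIM1 stood at 5.45 in parental hypoxia, PRKD2 at 5.60 in parental normoxia, and MIR3142HG and GDF15 at 5.70 and 5.75 in stem-like hypoxia. Across the 8996 genes the hypoxia folds of the cell states had a Pearson r of 0.33 and a Spearman rho of 0.28. Of the 39 and 33 genes that were higher in parental and stem-like hypoxia and measured in both, 15 were shared, against 0.133 for independent lists, and of the 7 and 16 that were lower, 0 were shared, against 0.0115 for independent lists. Of those 7, 85.7% had a log2 fold below 0 in stem-like cells too. Without background correction 2 genes passed a difference of 1 upward and 4 downward.

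**Figure D1:**
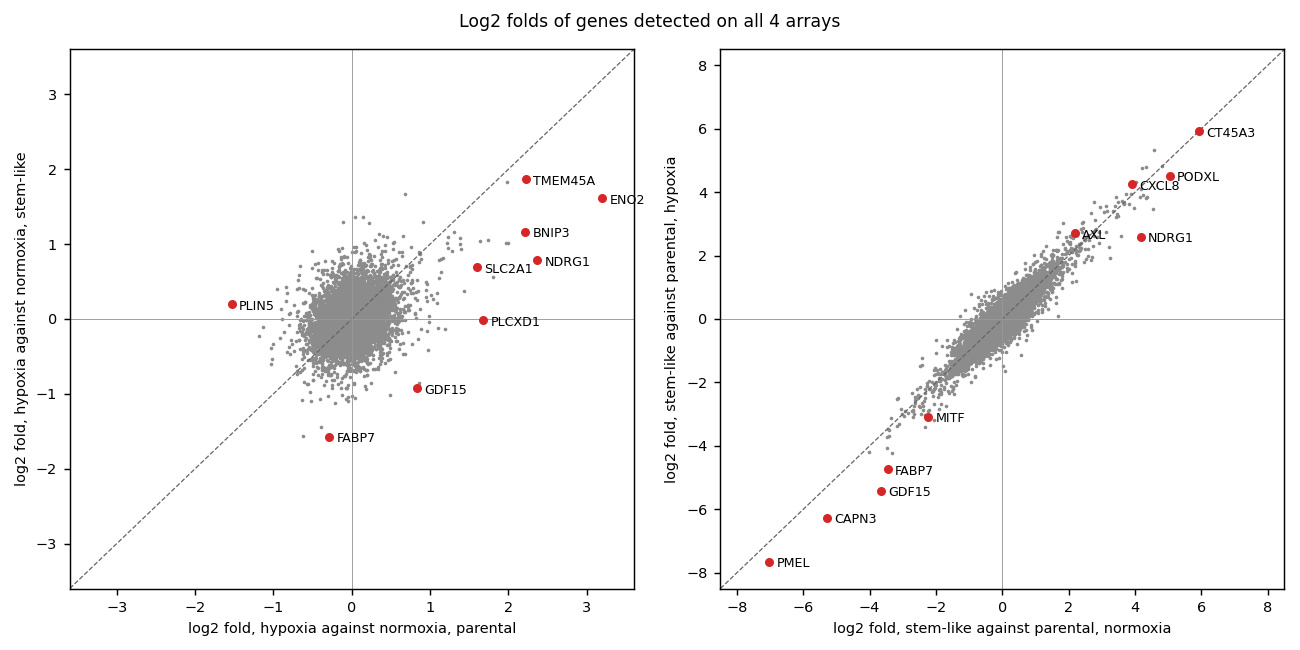
Each point is 1 of the 8996 genes detected on all 4 arrays; the left panel sets the log2 fold of hypoxia against normoxia in parental cells (x) against that in stem-like cells (y), and the right panel the log2 fold of stem-like against parental cells in normoxia (x) against that in hypoxia (y), with equality as a dashed line. ENO2 and NDRG1 lie to the right of the line on the left, with 3.20 and 2.37 in parental cells, and the right panel follows the line with PMEL at its lower end at -7.03 and -7.66.

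The comparison of the cell states asked what distinguishes the carmustine-selected cells from the line they came from. In normoxia, the stem-like cells carried far less RNA of the pigment cell program. PMEL, which encodes the fibrillar protein of melanosomes, was 130-fold lower, TYR, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, at least 62.5-fold lower, and MLANA, a melanosomal antigen gene, at least 9.34-fold lower. MITF, the master transcription factor of melanocytes, was 4.72-fold lower. The dedifferentiated melanoma, inflammatory and interferon response lists had median log2 folds of 1.38, 0.92 and 0.77. MGMT, which encodes the enzyme that removes alkyl groups from guanine, was not detected in parental cells and at least 6.73-fold higher in stem-like cells.

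In all, 711 genes were higher and 629 lower in stem-like normoxia among 10738, and 206 and 134 of them passed 4-fold. The SD of log2 folds over all genes was 0.79, against 0.26 and 0.29 for hypoxia in parental and stem-like cells. All 18 detected members of the melanocyte and pigment list had log2 folds below 0, 12 of them past 2-fold, and the median was -1.49 (percentile 0). CAPN3, a melanocyte-expressed calpain, was 38.7-fold lower. SOX10, a transcription factor of the neural crest and melanocyte lineage, stood at 1.73-fold lower and kept a normalized log2 level of 10.26 in stem-like normoxia. Of the dedifferentiated melanoma list, 11 of 19 members were higher and 0 lower, with a median of 1.38 (percentile 100). SOX9, a neural crest and cartilage transcription factor, was at least 23.6-fold higher, IGFBP3 10.9-fold, the matricellular protein gene THBS1 5.22-fold and the receptor tyrosine kinase gene AXL 4.53-fold.

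Of the inflammatory list, 8 of 19 members were higher, 3 lower and 8 within 2-fold, with a median of 0.92 (percentile 100). IL1B, which encodes interleukin-1 beta, was 18.3-fold higher, the neutrophil chemokine gene CXCL8 15.1-fold, IL6 6.04-fold and CXCL1 3.84-fold. Of the interferon response list, 11 of 23 members were higher and 0 lower, with a median of 0.77 (percentile 100). BST2, which encodes the antiviral protein tetherin, was 20.6-fold higher, IFITM1 at least 12.4-fold, MX1 8.64-fold and ISG15 3.28-fold. Antigen presentation genes had a median of 0.53 (percentile 99.9), with 4 of 15 higher and 0 lower, and lay inside the range of random lists without background correction and with the authors' table, at 0.19 each. It was led by the MHC class II pathway genes HLA-DMA at 15.6-fold and CD74 at least 13.0-fold. HLA-DRA had a log2 fold of 1.68 by its brighter probe and 4.0 by another. Leukocyte markers, of which 5 of 11 were detected on both stem-like arrays and 3 on each parental array, had a median of 0.67 (percentile 96.0).

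Genes of the epithelial-mesenchymal transition were split at the extremes. Of 12 detected members, 6 were higher and 1 lower, with a median of 0.97 (percentile 100), against 0.05 and inside the range of random lists with no detection filter. The calcium-binding protein gene S100A4 was 28.1-fold higher and the TGF-beta receptor gene TGFBR2 3.15-fold, while SNAI2, which encodes the transcription factor Slug, was at least 22.7-fold lower. Of the matrix and collagen list, 6 of 21 were higher and 1 lower, with a median of 0.39 (percentile 99.9). The collagenase gene MMP1 was 4.66-fold higher and the proteoglycan gene LUM 3.14-fold lower. The 3 detected fibroblast markers, LUM among them, had a median of 0.91, inside the central 95% of random lists. The list of cholesterol and fatty acid synthesis genes had a median of -0.43 (percentile 0.45), with 0 of 15 higher and 2 lower, LSS of the cholesterol pathway at 2.43-fold and ACACA of fatty acid synthesis at 2.15-fold.

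Genes associated with stem cells went both ways, with 3 of 18 higher, 4 lower and a median of -0.22 (percentile 11.7). PROM1 was at least 12.6-fold lower, ALDH1A1, an aldehyde dehydrogenase used as a stem cell marker, 2.82-fold lower, and the proto-oncogene MYC 2.88-fold lower. CD24 was 6.97-fold higher and the adhesion molecule gene MCAM at least 2.90-fold. The other members past 2-fold, ALDH1A3 at 2.48-fold higher and JARID2 at 2.14-fold lower, are named after their values were seen. SOX2, a pluripotency transcription factor placed in the dedifferentiated melanoma list here, was 2.20-fold higher. The hyaluronan receptor gene CD44 had a log2 fold of 0.01, the intermediate filament gene NES -0.36 and the histone demethylase gene KDM5B -0.63. ABCB5 and NGFR, both used as markers of melanoma subpopulations, were not detected on any of the 4 arrays.

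Of the DNA repair list, 3 of 21 members were higher and 0 lower, although the median was -0.29 (percentile 2.20). That median lay inside the range of random lists with a detection p-value under 0.05, at -0.27, and with no detection filter, at -0.27, and in hypoxia it was -0.03. Besides MGMT these were XRCC3, a homologous recombination gene, at 2.84-fold, and ERCC1, an excision repair nuclease gene, at 2.06-fold, whose other probes gave log2 folds from 0.40 to 2.01. Drug transport genes had a median of -0.47 (percentile 0.65), with the efflux pump gene ABCC3 at least 4.63-fold higher and ABCA1 at least 3.76-fold higher, and SLC67A1 3.06-fold and SLC7A5 2.46-fold lower. In the glutathione and NRF2 list, AKR1C3, of the same family of near-identical copies as AKR1C2, was at least 11.4-fold higher and GSTM2 4.0-fold lower, with a median of 0.02 (percentile 59.1). Of the cell cycle list, CCND1, which encodes cyclin D1, was 18.3-fold higher, while the list's median was -0.13 (percentile 11.1) and the proliferation marker MKI67 had a log2 fold of -0.34. Among p53 targets, GDF15 was 12.6-fold lower and CDKN1A, which encodes the cell cycle inhibitor p21, 3.42-fold higher, with a median of -0.22 (percentile 11.8). The hypoxia response list had a median of 0.42 in normoxia (percentile 99.9), with NDRG1 at 18.1-fold and STC2 at least 4.46-fold higher, MXI1 3.02-fold and WSB1 2.86-fold lower.

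Outside these lists the genes with the highest folds were CT45A3, a cancer-testis gene, at 61.3-fold, PODXL, which encodes the sialomucin podocalyxin, at 32.9-fold, STC1 at 23.9-fold, IGFBP5 at 23.0-fold, the growth factor gene TGFA at 20.2-fold and the keratinocyte envelope gene SPRR2D at 20.2-fold. A second probe of PODXL gave a log2 fold of 2.11 and one of SPRR2D 0.03. By bounds, SERPINA5 was at least 63.3-fold higher, CT45A1 at least 57.9-fold, the cancer-testis gene MAGEC2 at least 36.4-fold and the homeobox gene MSX1 at least 34.9-fold. Lower were the cholinesterase gene BCHE at 16.2-fold, ADCY1 at 11.1-fold, ARMCX2 at 11.0-fold, FABP7 at 10.9-fold and GAGE12D at 10.8-fold, and by bounds TMEM98 at least 46.8-fold and LZTS1 at least 22.2-fold. The second probe of ADCY1 gave a log2 fold of -1.09. CT45A3 and CT45A1 are near-identical copies of 1 family, so which member these probes measured is uncertain and they do not count as separate genes. GAGE genes are near-identical copies too, and all 12 GAGE symbols measured were past 2-fold lower with a median log2 fold of -2.81, so they cannot be counted as separate genes. Without background correction, 342 genes were higher and 250 lower.

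**Figure D2:**
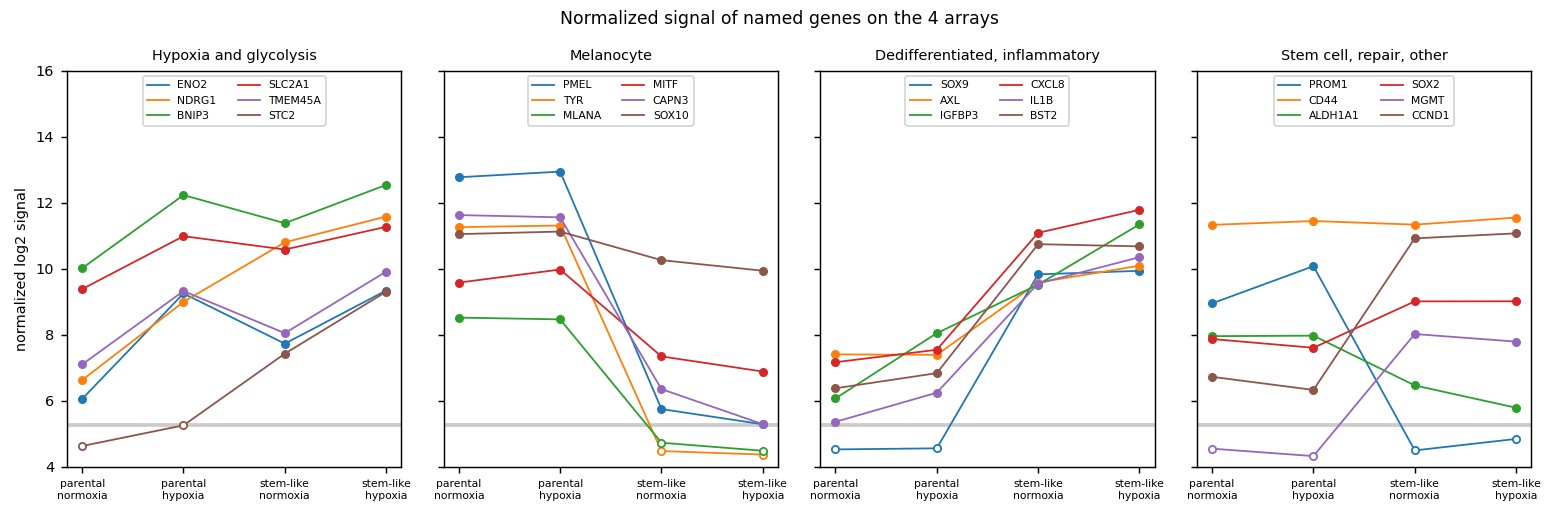
Normalized log2 signal (y) of 24 named genes on the 4 arrays (x), 1 array per group; filled points were detected, open points were not, the grey band is the detection floor of the arrays, and lines only join the points of a gene. PMEL stands at 12.77 in parental normoxia and 5.74 in stem-like normoxia, while SOX10 stands at 11.04 and 10.26.

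The cell states were also compared in hypoxia. PMEL was 202-fold lower, CAPN3 77.1-fold, GDF15 42.6-fold and MITF 8.53-fold, and TYR had a log2 fold of at most -6.09. MGMT was at least 5.79-fold higher, AXL 6.50-fold, CCND1 26.8-fold, CXCL8 18.9-fold and IL1B 17.2-fold. PROM1 was at least 28.9-fold lower and ALDH1A1 4.54-fold, while SOX2 was 2.66-fold higher and CD44 had a log2 fold of 0.10. In all, 790 genes were higher and 654 lower among 10979.

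Of the melanocyte and pigment list, 16 of 19 detected members were lower and 0 higher in hypoxia, with a median of -1.54 (percentile 0). SOX10 was 2.28-fold lower and OCA2, a melanosomal transporter gene, at least 9.76-fold. Of the dedifferentiated melanoma list, 14 of 19 were higher and 0 lower, with a median of 1.48 (percentile 100). Inflammatory genes had a median of 0.99 (percentile 100; 9 of 19 higher, 2 lower), interferon response genes 0.79 (percentile 100; 9 of 23 higher, 0 lower) and antigen presentation genes 0.72 (percentile 100.0; 6 of 15 higher, 0 lower). Leukocyte markers had a median of 0.84 (percentile 97.8; 2 of 5 higher) and fibroblast markers 1.34 (percentile 99.7; 2 of 3 higher, 1 lower). With a detection p-value under 0.05 these 2 medians were 0.26 and 0.19, both inside the range of random lists, and the leukocyte median lay inside it under 4 further settings, lowest with no detection filter at 0.06. The antigen presentation median lay inside it for genes detected on every array, at 0.31. The cholesterol and fatty acid synthesis list had a median of -0.59 (percentile 0.020), with MVD 2.36-fold and SC5D 2.28-fold lower, and 15 of 16 members lay below 0. In the stem cell associated list 5 of 18 were higher and 4 lower, with a median of -0.23 (percentile 8.89). The hypoxia response list had a median of 0.13 (percentile 87.8) and the glycolysis list 0.03 (percentile 53.3), so under hypoxia both lay inside the range of matched random lists.

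Other genes with high folds in this comparison were CT45A3 at 60.6-fold, STC1 at 40.4-fold, SERPINA5 at 29.2-fold, S100A4 at 28.1-fold, SPRR2D at 27.4-fold, PODXL at 22.9-fold and the calcineurin B homolog gene TESC at 22.8-fold. FABP7 was 26.7-fold lower, PHACTR1 18.8-fold, BCHE 18.1-fold, ARMCX2 16.6-fold and SNAI2 14.3-fold. By bounds, CT45A1 was at least 51.7-fold higher, MAGEC2 at least 40.0-fold, RAC2 at least 32.0-fold and MSX1 at least 29.4-fold, while TMEM98 was at least 51.8-fold and LZTS1 at least 24.1-fold lower. Across genes the folds of the cell states in normoxia and hypoxia had a Pearson r of 0.91 and a Spearman rho of 0.84. Of the 711 and 781 genes higher in normoxia and hypoxia among 10414 measured in both, 596 were shared, against 53.3 for independent lists, and of the 629 and 654 lower, 473 were shared, against 39.5. The comparisons use different arrays, and genes are not independent replicates. Without background correction 371 genes were higher and 281 lower.

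**Figure D3:**
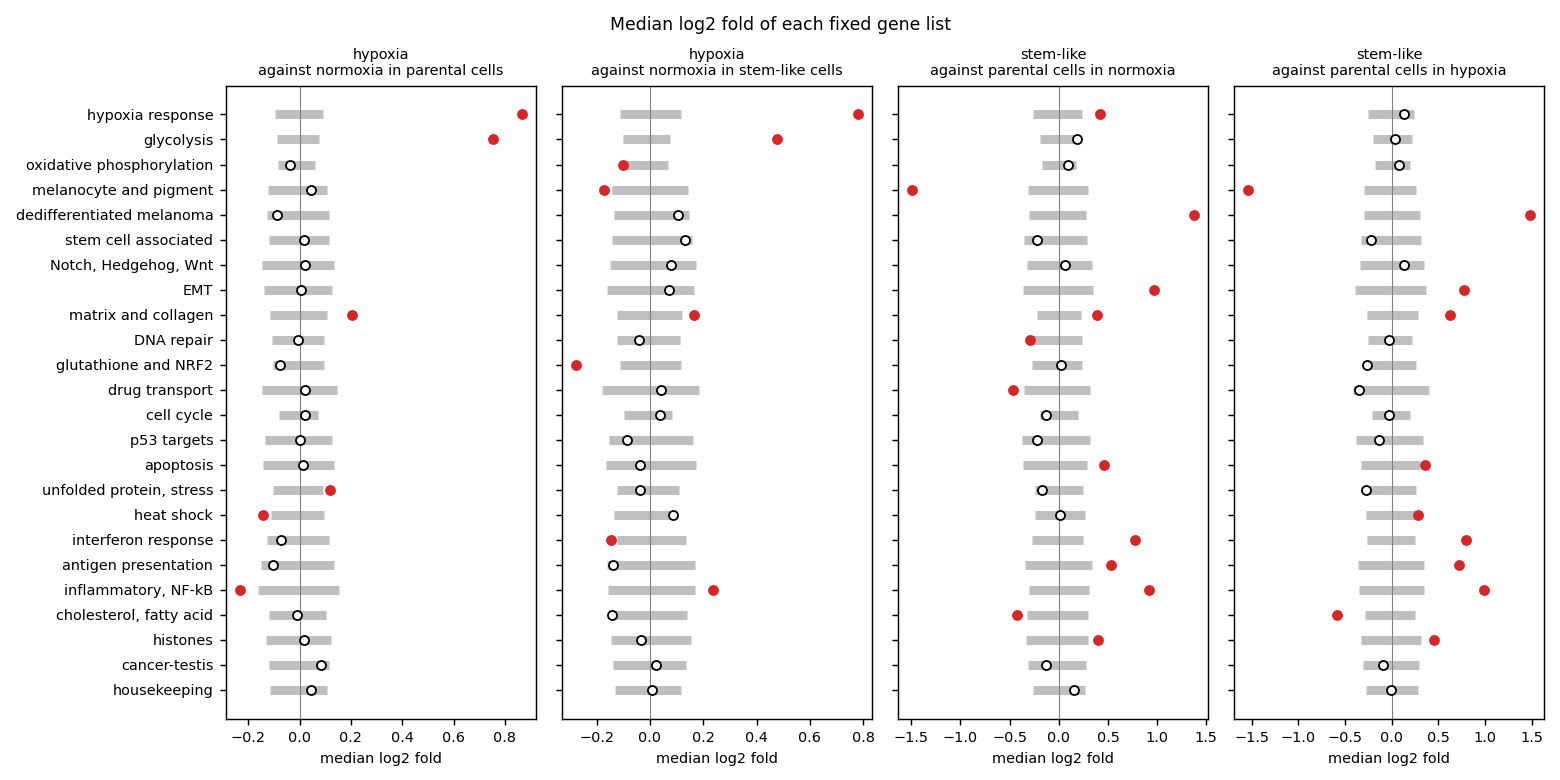
Median log2 fold (x) of 24 gene lists (y) in the 4 comparisons; grey bars span the central 95% of 10000 matched random lists, and red points lie outside them. The hypoxia response list stands at 0.87 and 0.78 in the hypoxia panels, and the melanocyte and pigment list at -1.49 and -1.54 in the panels of the cell states.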

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

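The test of the hypoxia exposure below was chosen after the result was seen; it replaced an earlier form, the list median in normoxia, which was 0.42 and could not have excluded the explanation. The tests of normalization and of signal compression were set before.

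Several genes had hypoxia log2 folds of opposite sign in the 2 cell states, each at least 0.5 from 0. This is what drew attention to them. They were taken from the genes named above for the largest differences, so genes outside those are not covered. Being picked for large differences, they do not show how common opposite signs were. With 1 array per group the difference was not tested for any of them. UNC45A, which encodes a myosin chaperone, stood at -0.51 in parental and 0.91 in stem-like cells, a difference of 1.43. NAV2 stood at -0.66 and 0.71, a difference of 1.37. MRTFB, a coactivator of serum response factor, stood at -0.67 and 0.58, a difference of 1.25. GDF15 went the other way, at 0.83 in parental and -0.93 in stem-like cells, a difference of -1.76. BEST1 did so too, at 0.85 and -0.86, a difference of -1.71. Each of these differences rests on 1 probe per gene, and some levels lay near the detection floor of 5.22 to 5.29. MRTFB stood at a normalized log2 level of 5.81 in parental hypoxia and 5.84 in stem-like normoxia. The level of GDF15 was 5.75 in stem-like hypoxia. The inflammatory list had medians of -0.23 over 13 detected members in parental and 0.24 over 18 in stem-like cells, so these rest on partly different genes. Both lay outside the central 95% of matched random lists. The list had a median difference of 0.32 over the 9 members detected on all 4 arrays, which was not tested either. Its parental median lay inside that range without background correction at -0.08, with a detection p-value under 0.05 at -0.09, with no detection filter at -0.0095 and with the authors' table at -0.08. Its stem-like median did so with no detection filter at 0.145, and the difference with a detection p-value under 0.05 at 0.19.

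A wider pattern was that 23 of the 26 members of the hypoxia response list detected on all 4 arrays had lower hypoxia log2 folds in stem-like cells, counted by sign alone. A difference of at least 1 was reached downward by 4 members and upward by 1. The pattern was not particular to this list, since the melanocyte and pigment list differed by -0.30 (-0.11 with no detection filter). Normalization or background correction is argued against, since the median difference of -0.31 stayed between -0.21 and -0.35 under other settings. These were no background correction, an offset of 50, median scaling and the authors' table, of which the first and last are nearly the same values. Compression of bright signals was not decided. The 24 of 26 members outside the brightest 10% of genes gave the same median of -0.31, but leaving out so few members can hardly move a median. A weaker hypoxia exposure of the stem-like culture may account for smaller folds and cannot be told apart from a property of the cells. Of the responding members detected on all 4 arrays, 9.52%, 2 of 21 (ADM and ANGPTL4), had a clearly larger fold in stem-like cells, too few to decide. Clearly larger means by over 2 of the combined SD of 0.30. WSB1, at log2 folds of 0.28 in parental and 0.84 in stem-like cells, came just under that cut. STC2 and COXFA4L2, which responded in stem-like cells, had no parental fold to compare. The list was already higher in stem-like normoxia, with a median of 0.42, while between the cell states in hypoxia it had a median of 0.13 (percentile 87.8). That baseline and the smaller folds share the 2 normoxia arrays, so they are not separate observations. No biological explanation of the baseline was tested.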

How the results depend on the processing

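No paired analysis was possible because no result comes from a test and the groups share only 1 replicate number; a fit of cell state and oxygen without their interaction, which would count any difference in hypoxia response as error, was not made. All alternatives were set before the data were examined. Of the main counts and correlations, 84 values kept their direction and stayed within 1.5 times the main count (correlations within their interval), and 40 moved. Of list medians, 1008 stayed, 63 moved and 2 reversed. A list median or single-gene fold stayed where it changed by less than the between-probe SD of its comparison, 0.20 to 0.29. For differences between hypoxia folds the limit was the combined SD of 0.30. Many list medians are smaller than these limits and could fall to 0 and still stay, so the 1008 say little about them. A median that stayed could still come to lie inside the range of random lists. With a detection p-value under 0.05, 3 medians moved while 9 came to lie inside it. Of single-gene folds, 3656 stayed, 910 moved and 0 were labelled reversed. That label may leave out sign changes of values near 0. Without background correction 283 single-gene folds moved and 301 stayed, as with the authors' table, which holds nearly the same values. With an offset of 50, 189 moved and 395 stayed. Genes detected on every array was not run for the differences and correlations, which need all 4 arrays already.

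Without background correction, genes higher in hypoxia numbered 19 in parental and 12 in stem-like cells and genes lower 1 and 2; genes higher in stem-like cells numbered 342 in normoxia and 371 in hypoxia and genes lower 250 and 281. Differences between hypoxia folds past 1 numbered 2 upward and 4 downward, and the across-gene correlations were 0.388 for hypoxia folds and 0.926 for the cell states. With the authors' table these numbers were 20, 11, 1 and 2 for hypoxia, 344, 372, 254 and 283 for the cell states, 3 and 5 for the differences, and 0.387 and 0.926 for the correlations. With an offset of 50, 24 genes were higher and 6 lower in stem-like hypoxia, 1 was lower in parental hypoxia, 402 and 415 were lower in stem-like cells in normoxia and hypoxia, differences numbered 6 and 12, and the correlations were 0.362 and 0.919. The first 2 settings leave background in the signal and a larger offset adds a constant to it, and each shrinks folds by construction.

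With median scaling, 34 genes were higher in stem-like hypoxia. With a detection p-value under 0.05 the correlation of hypoxia folds was 0.302. With no detection filter, 15 genes were lower in parental hypoxia, 122 and 90 differences passed 1 upward and downward, and the correlations were 0.196 and 0.880; undetected genes enter here. The 2 reversed medians belong to that setting, matrix and collagen in parental hypoxia at -0.0041 and the metallothionein list between the cell states in hypoxia at -0.0121, and the cause was not tested.

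Of the 53 list medians outside the central 95% of random lists, 14 lay inside it with no detection filter, 9 with a detection p-value under 0.05, 8 without background correction, 7 with the authors' table, 4 with the mean of the detected probes, and 1 each with an offset of 50, median scaling and genes detected on every array. The 53 come from a separate random draw and include the p53 target difference, inside at percentile 2.53 in the main draw. It is among the 9 and among the 4. Medians that came to lie outside numbered 9 with the mean of the detected probes, 8 with no filter and 7 with the authors' table. They numbered 5 each without background correction and with an offset of 50, and 4 each with median scaling and a detection p-value under 0.05. Genes detected on every array gave 3.

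The share of higher among all genes past 2-fold was 83.3% in parental hypoxia, against 95.0% without background correction, 96.4% with an offset of 50 and 95.2% with the authors' table. In stem-like hypoxia it was 73.2%, against 85.7% without background correction and 84.6% with the authors' table. The other settings gave 78.6% to 86.0% in parental and 65.4% (median scaling) to 80.0% in stem-like hypoxia. Between the cell states the share was 53.1% in normoxia and 54.7% in hypoxia; it was highest with median scaling, at 60.4% and 58.4%, and lowest for genes detected on every array, with 490 higher and 490 lower in normoxia and 52.3% higher in hypoxia. Median scaling put the median log2 fold of all genes at -0.04 in stem-like hypoxia and at 0.08 and 0.04 between the cell states in normoxia and hypoxia, the largest shifts of any setting. Low signal over background limits the dim genes most.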

Other observations

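The tests of other cell types and of another cell line below were chosen after the results were seen, and the runs of genes named were picked by their values; the other tests were set before. The test of other cell types was rewritten more than once after values were seen, and a form that rested on broadly expressed genes of the pigment list was dropped.

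Lists not described above mostly lay near 0 in hypoxia. In parental hypoxia the medians were -0.04 for oxidative phosphorylation, 0.02 for Notch, Hedgehog and Wnt signalling, 0.01 for apoptosis, -0.19 for the metallothionein list (MT1E, MT1X, MT2A and the zinc exporter gene SLC30A1), 0.02 for histones, 0.08 for cancer-testis genes, 0.05 for housekeeping genes and 0.17 for neural crest and neural genes. Between the cell states in normoxia, cancer-testis genes went both ways, with 4 of 18 higher, 4 lower and a median of -0.13. MAGEA1 was at least 27.1-fold higher and CTAG2 at least 13.0-fold lower, although a second probe of CTAG2 gave -0.09. In the Notch, Hedgehog and Wnt list 5 of 16 were higher and 2 lower, with a median of 0.06, and DKK1, which encodes a secreted Wnt inhibitor, was 13.3-fold higher, SFRP1 4.41-fold and NOTCH3 3.02-fold.

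Of apoptosis genes, 4 of 16 were higher and 2 lower in stem-like normoxia, with a median of 0.46 (percentile 99.8), against 0.26 and inside the range of random lists with no detection filter. MCL1, which encodes a survival protein, was 2.90-fold higher, and BCL2 2.73-fold lower. In the unfolded protein and integrated stress list, with a median of -0.17, the chaperone gene HSPA5 was 2.92-fold higher and VLDLR 5.40-fold lower. The collagen chaperone gene SERPINH1 was 2.70-fold higher in a heat shock list with a median of 0.01. The histone list had a median of 0.40 (percentile 99.5), oxidative phosphorylation 0.09, glycolysis 0.18, the metallothionein list 0.43, housekeeping genes 0.15 and neural crest and neural genes -0.21, with NCAM1 3.31-fold lower. On both stem-like arrays, of the fibroblast markers 3 of 11 were detected (PDGFRL, LUM, FAP), of keratinocyte markers 2 of 9 (KRT10, DSP), of endothelial markers 2 of 10 (TEK, ESAM) and of leukocyte markers 5 of 11 (CD14, LYZ, CD68, FCGR3A, LAPTM5), and CD14 was 4.95-fold higher in stem-like normoxia.

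The lower pigment genes could have technical sources. Faulty probes are argued against for the list genes with a further detected probe, since 100% of 10 further probe comparisons had the sign of the first. These 10 are counted over normoxia and hypoxia together, so the same probe can enter for both. Cells of another type in the stem-like culture could not be told apart from a change in state by these markers. The highest share detected, 45.5% of leukocyte markers, has an exact binomial interval from 16.7% to 76.6%, which holds 50%. That interval treats chosen markers as independent draws, which they are not, so it does not measure how many other cells there were. On each parental array 3 of the 11 leukocyte markers were detected too. SOX10, of the neural crest and melanocyte lineage, had a log2 fold of -0.79 against -7.03 for PMEL, which cells without SOX10 in such numbers would not leave, but it is 1 gene. Another cell line under the stem-like label stays open as well, since levels correlated at r = 0.930 across genes and no genotype was analysed here, so whether the carmustine-selected state is the source stays untested.

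Neighbouring genes shifted together between the cell states. Over 8985 genes in genomic order, folds of genes 10 places apart correlated at 0.0617 in normoxia, above the highest of 1000 random orders at 0.0407, which argues against a chance order. Noise tied to position on the genome that differs between arrays of 1 cell state is argued against, since hypoxia folds gave at most 0.0194. A bias of that kind shared by both arrays of a cell state would cancel in hypoxia folds, so it stays open. Clusters of related genes are argued against only as the whole source. Genes 20 places apart still gave at least 0.0430, in hypoxia, where the highest random order gave 0.0359. Adjacent genes correlated more, at 0.199 in normoxia and 0.191 in hypoxia, so a contribution of such clusters stays open. The highest run of 31 genes, from WDR20 to CRIP2 with XRCC3 inside it, had a median log2 fold of 1.01 in normoxia and 1.15 in hypoxia, and the lowest, from BLOC1S5 to E2F3 with TFAP2A, PHACTR1 and JARID2, -0.89 and -0.87, against 0.52 and -0.55 as the extremes of 100 random orders. As a hypothesis, gains and losses of chromosome segments may separate the stem-like cells from the parental line; no copy number was analysed here, and another cell line, above, would give such runs too.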
